A study of Rattus norvegicus with 6 samples.

How the data were processed

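Thalamus RNA of 6 rats was sequenced, 3 after bilateral temporomandibular joint injections of CFA and 3 after saline, and groups and replicate numbers were taken from the sample titles. The column name of CFA replicate 3 begins with another letter than those of CFA replicates 1 and 2, while the saline columns share 1 letter. What the letters stand for is not given in the sources used here, so a batch within the CFA group cannot be told. The series labels describe these as separate animals. Per the labels' protocols, RNA was purified with poly-T beads, fragmented, copied with random hexamers and amplified by PCR. circRNAs have no poly(A) tail, so a selection of this kind would lose most of them; the labels' protocols name no RNase R treatment or rRNA removal. The tools named in the submitters' processing notes are HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2 1.20.0. The circRNA caller and the genome build are not given in the sources used here.

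The table deposited by the authors holds, per the file headers, a read count per circRNA and library, and these raw counts were used for all tests. The same table holds a normalized value per library, named TPM in the header. In each library 1 read was worth the same value for every circRNA, so this unit is RPM, reads scaled to 1000000 per library, without a length term. The totals implied by the authors' RPM exceeded the sums of the table slightly: 99.5% to 99.6% of those reads were in the table. RPM printed here were computed from the counts and the table's own totals. The lowest count above 0 was 2, so counts of 1 were removed or never made before deposit, and a listed 0 may be 1 read. A deposited sequence file gives each circRNA's position, strand, spliced sequence and a 58 nt junction sequence, and starts counted from 0 there had 1 added.

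The depth was 573696 to 1176178 circRNA reads per library. The reads were amplified by PCR and carry no molecular identifiers, so counting error is a lower limit of the error. Among circRNAs with a median of at least 50 RPM in the other libraries, 1.18% of values were 0, where Poisson counting gives 3.37e-11 such zeros in all. The Poisson value leaves out differences between animals. Libraries of the same group correlated at 0.685 to 0.714 (Pearson's r of log2(RPM + 1) over circRNAs, which are not independent replicates) and libraries of different groups at 0.683 to 0.711. The lowest chi-square per degree of freedom between any 2 libraries was 10.1, so none was a repeat of another within sampling noise. Same-numbered libraries of both groups did not deviate together (r from -0.09 to 0.02, where pairing asks for more than 0.1), so this check gave no sign that the numbers pair the rats. It cannot exclude a pairing.

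circRNAs with at least 10 counts summed over the 6 libraries were tested, 22426 of 32445, which hold 98.9% of the reads. edgeR 4.0.16 was run in R 4.3.3 with TMM normalization, robust dispersions and the robust quasi-likelihood fit, comparing CFA with saline without covariates, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors were taken as the log2 fold change over the root of the F statistic and are approximate. The number of circRNAs seen was compared after 20 seeded thinnings to the smallest library, and shares of reads in circRNAs of 1000 nt or more were compared between libraries, each with an exact two-sided permutation test. The seeds of 16 miRNAs, positions 2 to 8, were searched in the circular sequences, across the back-splice junction. circRNAs with 2 or more matches formed a set, tested with camera in limma 3.58.1 at a preset correlation of 0.01, and beside it with an estimated one. A set needed 5 members, which left out miR-132 with 1 circRNA. Each set's median was also placed among 10000 random sets matched on length. The sequences run in the sense direction, judged by reading frames without a stop codon over the whole sequence, with no start codon asked for. This covered 21652 circRNAs of 300 to 600 nt, leaving out those with a sequence as long as the genomic span. Such a frame was found as given in 51.5% of those on the plus strand and 52.6% on the minus strand. In reverse it was found in 4.13% and 4.28%.

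Tests at the level of host genes were planned, with 11 pathway lists and 12 cell type marker lists of host genes. The identifiers are not paired with gene names in the files used here, and 0 of them matched the reference table of rat gene names, so these lists were not analysed here. In their place, and chosen after the data were seen, counts were summed over loci, the runs of circRNAs that overlap on the same strand, and 7581 loci with at least 10 counts were tested in the same way. The planned rule for named circRNAs took up to 12 per direction with the largest change among those past the threshold whose values do not overlap between groups, filled to 10 with the smallest p, and the 10 most abundant. Since no names are paired, 2 identifiers per direction are printed, those that head the rule's lists, and others are given by position or as counts. Of the 28 called circRNAs 1 has a junction within 10 nt of another at both ends, where reads can be assigned to either; 686 of all circRNAs are of this kind.

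On simulated counts drawn from the real means and library sizes, the circRNA test run on 18623 circRNAs recovered 1.49% of 2-fold, 19.4% of 4-fold and 62.1% of 8-fold changes, with 20 false calls. The locus test run on 6758 loci recovered 1.49%, 55.2% and 84.8%, with 10 false calls. In both simulations, changes were placed only in well-read circRNAs or loci, above the minimum of 10 counts, so recovery over all those tested may be lower. For the miRNA sets, camera called 10 of 10 sets of 40 circRNAs shifted 2-fold and 0 of 140 unshifted sets. These sets were drawn without correlation between circRNAs, and the miR-146 and miR-21 sets are smaller, at 24 and 10 circRNAs. Most 2-fold and 4-fold changes of single circRNAs were thus missed at this depth and spread.

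Alternatives fixed before the data were examined were RLE size factors, total counts alone, DESeq2 1.42.0, no filter, edgeR's filterByExpr, at least 30 counts, a fit that is not robust, the replicate number as a block, unadjusted p-values and leaving out each library in turn. For the other measures they were other count minimums, no thinning, shares of circRNAs instead of reads, and 1 or 3 seed matches. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for the remaining steps.

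The rules for 2 explanations were rewritten after their outcomes were known. For deeper saline libraries, the first test scaled the reads of the 7 lower unspliced circRNAs to the smallest library and argued against depth, but the 7 were chosen for having no CFA reads. The share of unspliced circRNAs at equal depth took its place, first with an exact p below 0.05 required, which 3 rats against 3 cannot give and which left depth open. The next rule asked for a difference of more than 2 SE without overlap of the groups, which was met and argued against depth. The rule now first asks that thinning remove at least 10% of the circRNAs of the deepest library. It removed 2.43%, so the test is void and depth stays open. This share was counted at 1 read or more, while the smallest library lists no count below 2. For CFA replicate 1 at the chromosome 3 locus, the first rule asked only that each log2 fold change without it be more than 2 SE above 0, which was met. The rule now also asks that both other CFA libraries lie above every saline library for each of the 3 circles, which was not met and leaves this explanation open.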

Results

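Circular RNAs (circRNAs), closed transcripts formed when a downstream splice site joins an upstream one, were counted in the thalamus of 6 rats. The thalamus relays sensory input, orofacial pain included, to the cortex. In 3 rats both temporomandibular joints were injected with 50 µL of CFA (complete Freund's adjuvant, used to provoke lasting joint inflammation), and in 3 rats with saline. Injections were given 2 times per week and tissue was taken after 14 days. The deposited table gave read counts for 32445 circRNAs. The CFA libraries held 656598, 651615 and 903443 circRNA reads, and the saline libraries 573696, 1176178 and 936062. The files used here do not pair the circRNA identifiers with host genes, so positions are given as in the deposited sequence headers, whose genome build is not given in the sources used here.

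Thalamic circRNAs were mostly short and came from a smaller number of transcribed regions. The 32445 circRNAs fell into 9564 loci, defined here as runs of circRNAs that overlap on the same strand. A locus with more than 1 circRNA was found 5117 times, and the richest locus held 49. Median spliced length was 384 nt, with quartiles of 311 and 478 nt, over a median genomic span of 11167 nt. Among the 3290 loci with several circRNAs and at least 100 reads, the leading circRNA held a median of 61.8% of the locus reads. Only 770 circRNAs (2.37%) were 1 segment with a sequence as long as the genomic span, called unspliced here. Circles of 1 exon meet this definition too, and the sources used here give no exon positions to set them apart. A core of 8335 circRNAs (25.7%) had reads in all 6 libraries and held 87.6% of the reads, whereas 9452 were seen in 1 library each.

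The most abundant circRNAs differed between the groups by less than the test could call. The leading one, a 1345 nt circle from chromosome 9, 94463647 to 94481167 on the plus strand, reached 13652 ± 644 RPM (reads per 1000000 circRNA reads) after CFA and 14781 ± 1621 RPM after saline (mean ± SD, n = 3 each). A 531 nt circle from chromosome 7, 30727478 to 30735182, followed with 11037 ± 2447 and 12315 ± 4264 RPM. A 1016 nt circle from chromosome 1, 204959173 to 204961691, had 6303 ± 1460 and 6887 ± 984 RPM. Across the 10 most abundant circRNAs the log2 fold changes (CFA minus saline) lay between -0.31 and 0.63. The smallest adjusted p among them was 0.912 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

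The central comparison asked which thalamic circRNAs differ after 14 days of joint inflammation. Of 22426 circRNAs tested, 14 were higher and 14 lower in CFA than in saline rats. Of these 28, 21 had no reads in any library of 1 group: 9 were read only in CFA libraries and 12 only in saline libraries. Of the 28, 7 were read in 1 library alone. Over all circRNAs tested the median SE of the log2 fold change was 1.68. Of the 1708 with reads in all 6 libraries and more than 100 RPM by edgeR's mean, 91.2% had a log2 fold change within 0.5 of 0, at a median SE of 0.35.

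Higher in CFA was novel_circ_0005029, a 443 nt circle from chromosome 12, 40388299 to 40397763 on the minus strand. It had 26, 16 and 13 reads in the CFA libraries, or 26.2 ± 12.7 RPM (SD, n = 3), and is listed at 0 in the 3 saline libraries (adjusted p = 0.0349, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). This call was lost in DESeq2 and whenever a library other than CFA replicate 3 was left out, although its log2 fold change of 7.39 was 6.92 in DESeq2 and no lower in those other fits. Also higher was novel_circ_0011300, 309 nt, from chromosome 16, 26755234 to 26780008 on the plus strand, with 13, 112 and 19 reads after CFA against 0, 5 and 5 after saline. Its log2 fold change was 4.17 ± 0.67 (SE; adjusted p = 4.12e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Without CFA replicate 2 that log2 fold change was 2.51 and the call was lost. It was also lost without saline replicate 1, at 3.74.

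The decreases that head the naming rule were circRNAs read in every saline library and in no CFA library. For novel_circ_0006907, a 440 nt circle from chromosome 13, 83256334 to 83257043 on the minus strand, the saline libraries held 20, 61 and 56 reads, or 48.8 ± 12.8 RPM (SD, n = 3). Its adjusted p was 4.92e-08 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For novel_circ_0028195, an unspliced 703 nt segment of chromosome 3, 154869699 to 154870401 on the plus strand, they held 30, 28 and 49 reads, or 42.8 ± 16.5 RPM, with an adjusted p of 3.61e-06 in the same edgeR test with Benjamini-Hochberg adjustment. Both are listed at 0 in the 3 CFA libraries. Together with a 788 nt unspliced segment from chromosome 20 they were the 3 circRNAs, all lower in CFA, that stayed called when any 1 library was left out and that DESeq2 also called, although none passed in edgeR with at least 30 counts or with filterByExpr.

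Unspliced segments were frequent among the decreases. Of the 14 lower circRNAs 7 were of this kind, 643 to 935 nt long, against 0 of the 14 higher ones and 560 of the 22426 tested. In 12 of the 28 circRNAs the RPM values of both groups did not overlap. The 28 were called for a difference between the groups, so their share cannot be set against chance. Over all tested circRNAs the share was 6.63%. Chance alone gives 10% with 3 libraries against 3, but only where no values are tied. A value of 0 in both groups was counted as overlap, which lowers the chance share by an amount that was not computed. The 6.63% is therefore not read as a deficit.

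Without adjustment, 276 circRNAs were higher and 326 lower at p below 0.05 in edgeR, 602 in all. Evenly spread p-values would give 1121 over 22426 tests, but sparse counts need not give such p-values. The 9 other ways of splitting the 6 libraries 3 against 3 gave 609 to 1314, so CFA against saline gave the fewest. These splits were chosen after the results were seen, and 10 splits are too few for a share below 0.05. DESeq2 called 4 circRNAs, all lower, edgeR called 0 with at least 30 counts (237 at an unadjusted p below 0.05), and edgeR called 15 without saline replicate 1. The table lists no count of 1, so a listed 0 may stand for 1 read.

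**Figure D1:**
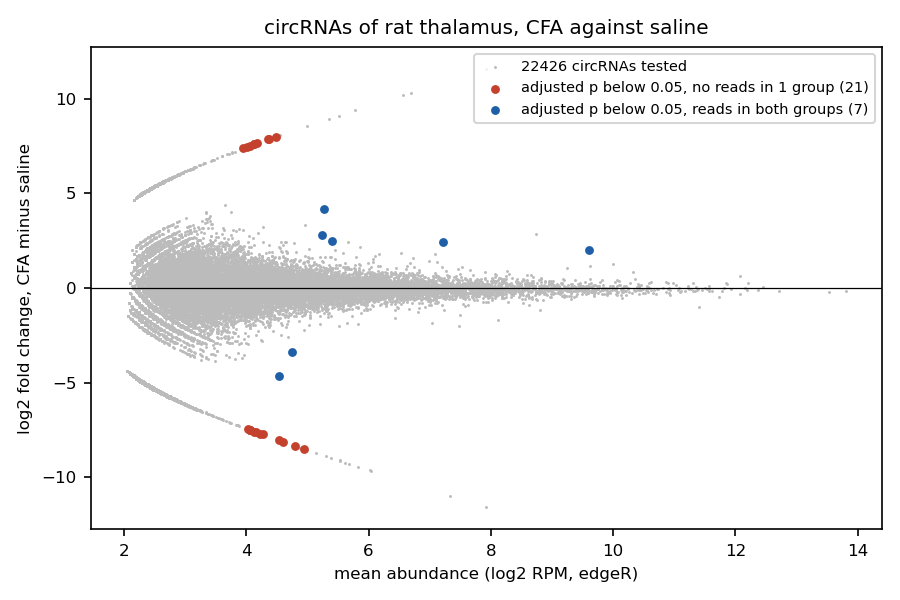
Each point is a circRNA, placed by its mean abundance (log2 of edgeR's mean RPM over 6 libraries) and its log2 fold change (CFA minus saline, n = 3 each) for the 22426 circRNAs tested. Red points mark the 21 circRNAs past the adjusted threshold without reads in a whole group, whose fitted fold changes depend on edgeR's prior count, and blue points the 7 others.

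**Figure D2:**
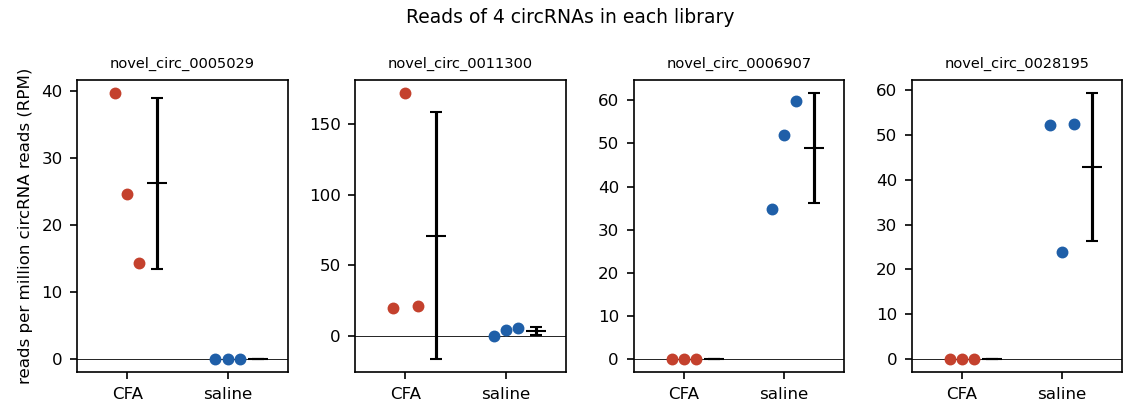
Points give the RPM of 4 circRNAs in each of 3 CFA and 3 saline libraries; the bars are the mean ± SD. Those of novel_circ_0005029 and novel_circ_0011300 were higher in CFA, the latter carried mainly by 112 reads in 1 library, and novel_circ_0006907 and novel_circ_0028195 are listed at 0 in all CFA libraries.

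Of the 28 calls, the 2 above 100 RPM, both higher in CFA, came from a locus on chromosome 3, 133012095 to 133122763 on the minus strand, that held 16 circRNAs. A 354 nt circle from 133108204 to 133122763 had 1479, 757 and 310 reads after CFA and 183, 342 and 267 after saline, a log2 fold change of 2.03 ± 0.32 (SE; adjusted p = 3.77e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). A 385 nt circle that shares the end at 133122763 and starts at 133099125 had 352, 96 and 50 against 26, 65 and 32 reads, a log2 fold change of 2.41 ± 0.42. A 678 nt circle with this end, from 133043468, had 1041, 375 and 70 against 83, 114 and 59 reads and did not pass, at 2.87 ± 1.23 (adjusted p = 0.912 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The 3 other tested circles with this end had log2 fold changes between -0.06 and 0.79 and did not pass either. The 678 nt circle was singled out after its values were seen. It passed in the fit that is not robust (adjusted p = 0.0137), with the replicate block (3.13e-05) and without CFA replicate 3 (2.78e-17), each in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without CFA replicate 1 the log2 fold changes were 1.26 for the 354 nt circle, 1.09 for the 385 nt circle and 1.62 for the 678 nt circle, and none was called. The 354 nt circle was also not called in DESeq2, nor when CFA replicate 2 or any 1 saline replicate was left out, although its log2 fold change stayed at 2.02 to 2.11. In edgeR with at least 30 counts the SE rose to 0.59 for the 354 nt circle and 0.77 for the 385 nt circle. With filterByExpr it was 0.57 and 0.76. Neither circle was called in these 2 fits. The SE of 0.32 and 0.42 thus depend on the sparse circRNAs fitted alongside and may understate the spread between rats. The 385 nt circle was not called in DESeq2 or without saline replicate 1 or 3, at log2 fold changes of 2.44, 2.35 and 2.26.

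**Figure D3:**
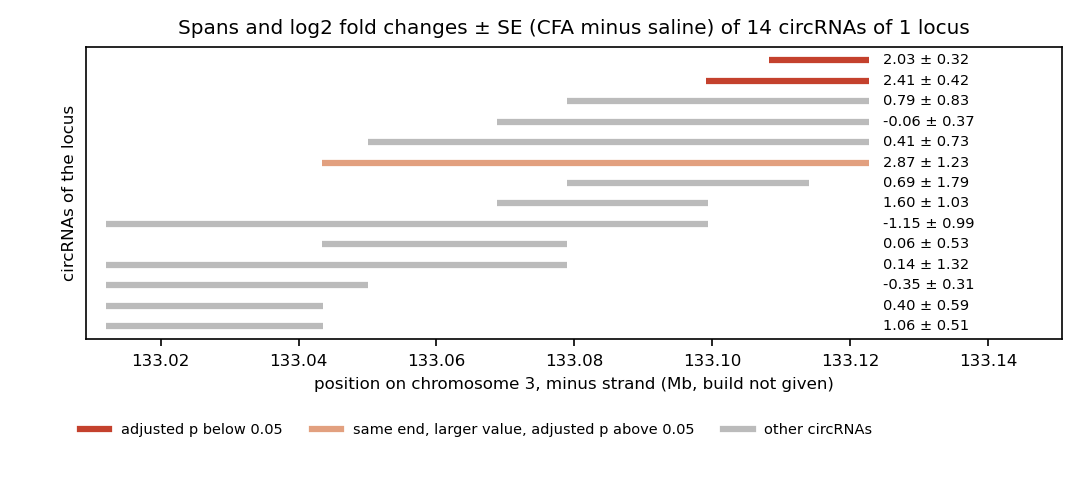
Horizontal bars span the 14 tested circRNAs of the chromosome 3 locus (position in Mb), with the log2 fold change ± SE (CFA minus saline, n = 3 each) at the right. Both called circRNAs, 2.03 ± 0.32 and 2.41 ± 0.42, share the right-hand end with 3 circRNAs between -0.06 and 0.79 and with the one at 2.87 ± 1.23.

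Summed per locus, 1 of 7581 loci tested was lower and 0 were higher in CFA. The test recovered 1.49% of simulated 2-fold changes of well-read loci. The lower locus was that of novel_circ_0028195 itself, its sole circRNA (adjusted p = 0.0423, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among loci with several circRNAs, that with the smallest p toward higher values lay on chromosome 2, 109304854 to 109366472 on the minus strand, with 9 circRNAs. It held 188 ± 27.8 RPM after CFA and 71.1 ± 15.8 RPM after saline (SD, n = 3 each), a log2 fold change of 1.37 ± 0.34. A locus of 9 circRNAs on chromosome 19, 12652625 to 12713398 on the minus strand, held 419 ± 121 and 846 ± 163 RPM, a log2 fold change of -1.03 ± 0.26. Neither passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at unadjusted p of 0.000540 and 0.000670. The summed chromosome 3 locus had a log2 fold change of 1.27 ± 0.58 and did not pass. The call of the chromosome 3 unspliced segment at the level of loci was lost whichever of the 6 libraries was left out, while its log2 fold change of -8.13 stayed between -8.29 and -7.89, and 59 loci were higher and 66 lower at an unadjusted p below 0.05 in edgeR.

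The number of circRNAs seen in the thalamus did not differ detectably. Thinned to the 573696 reads of the smallest library, CFA libraries showed 17363 ± 1751 circRNAs and saline libraries 18493 ± 3325 (SD, n = 3 each; exact two-sided permutation test, p = 0.7). These were counted at 1 read or more, where thinning removed only 2.43% of the circRNAs of the deepest library. Thinned libraries can hold counts of 1 and the smallest library lists none below 2, so this count is not like for like. At 2 reads or more the deepest library fell from 21677 to 19460 circRNAs. The groups then had 16930 ± 1364 (CFA) and 17567 ± 2477 (saline, SD, n = 3 each, exact two-sided permutation test, p = 0.7). At 1 read or more and without saline replicate 2, the difference turned to 198 more circRNAs in CFA. Total circRNA reads were 737219 ± 143976 and 895312 ± 303301 (exact two-sided permutation test, p = 0.6). With 3 rats against 3 this test cannot give a p below 0.1. Even circRNAs that were abundant elsewhere were at times listed at 0 in a library: 216 of 18267 values were 0 where the other 5 libraries had a median of at least 50 RPM, 110 in CFA and 106 in saline libraries.

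**Figure D4:**
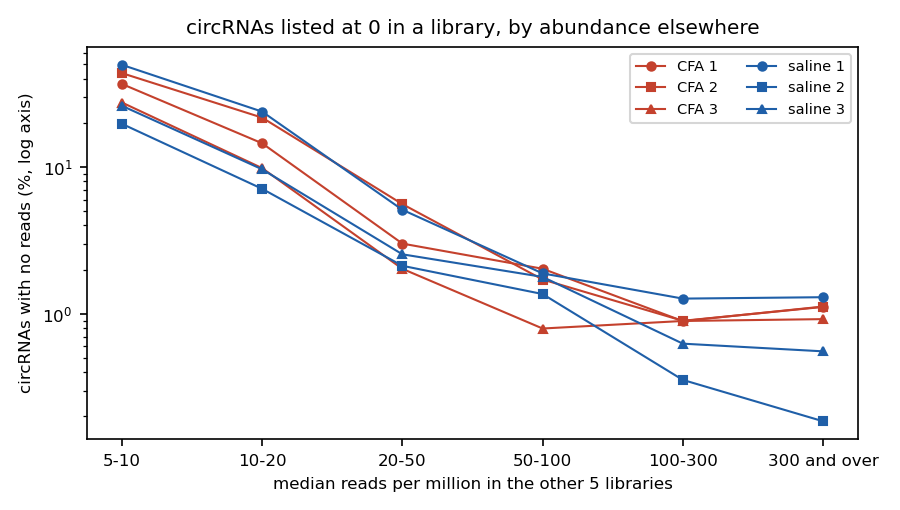
For each of the 6 libraries, the percentage of circRNAs listed at 0 (log axis) is drawn against the circRNAs' median RPM in the other 5 libraries. Saline replicate 1 had the largest percentage at 5 to 10 RPM, 49.7%, and saline replicate 2 the smallest, 19.7%. At 300 RPM and over saline replicate 2 still had 0.186%.

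The share of reads in long circles did not differ detectably. CircRNAs of 1000 nt or more held 6.20 ± 0.571% of reads after CFA and 6.64 ± 0.462% after saline (SD, n = 3 each; exact two-sided permutation test, p = 0.3). As a share of the circRNAs seen they made up 1.23 ± 0.0345% and 1.32 ± 0.0215%, lower in each CFA library than in each saline library (exact two-sided permutation test, p = 0.1, the smallest possible). Unspliced segments, a class added after the data were seen, made up 2.17 ± 0.0507% and 2.38 ± 0.109% of the circRNAs seen, again without overlap (exact two-sided permutation test, p = 0.1).

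The study also asked which miRNAs its circRNAs could bind. Sets of circRNAs with at least 2 seed matches were tested for 15 miRNAs, and 0 sets passed in camera. For miR-146, a brake on innate immune signalling, the 24 circRNAs had a median log2 fold change of 0.48, 16 of 24 above 0 (adjusted p = 0.441 in limma's camera with Benjamini-Hochberg adjustment). Without CFA replicate 3 this median was 0.11. The 10 circRNAs of the miR-21 set, a miRNA raised in many inflamed tissues, had a median of 0.60 (adjusted p = 0.441 in the same camera test with Benjamini-Hochberg adjustment), which was 0.24 without CFA replicate 1 and 0.37 without saline replicate 1. Both are values of sets that did not pass, and miR-146 was the 1 set with an unadjusted p below 0.05. The sets of miR-155 and miR-223, both tied to immune cells, had medians of -0.36 and -0.15. Those of the neuronal miRNAs miR-124, miR-9, miR-128, miR-138 and miR-7 had medians of -0.17, -0.19, -0.24, -0.15 and -0.20, although camera's direction for miR-7 was upward. Medians were -0.31 for let-7, 0.16 for miR-183, -0.14 for miR-103, -0.33 for miR-29, -0.14 for miR-34 and -0.13 for miR-125. For the 13 sets other than miR-146 and miR-21 the adjusted p in camera lay between 0.621 and 0.893 with Benjamini-Hochberg adjustment. With an estimated correlation the adjusted p was 0.945 for each of the 15 sets. Among members, 0 circRNAs of any set passed over all circRNAs tested, and adjusted over the list alone 1 passed in the miR-146 set and 1 in the miR-34 set. A seed match is a property of the sequence and does not show binding.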

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

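Settings chosen after the data were seen were circRNAs or loci with reads in all 6 libraries, circRNAs without unspliced segments, all settings for loci and for the unspliced share. With RLE size factors 28 circRNAs were called, all of them among the 28 of the main fit. With total counts alone 28 were called, 27 of them shared with the 28. There were 32 calls without a filter (28 shared), 32 in the fit that is not robust (11 shared) and 21 without unspliced segments. DESeq2 called 4, all lower in CFA and 3 of them shared, and left 33 adjusted p-values as NA. edgeR called 0 with filterByExpr (130 at an unadjusted p below 0.05), 0 with at least 30 counts (237 at an unadjusted p below 0.05) and 0 with reads in all 6 libraries (234); filterByExpr kept 12 of the 28 called circRNAs and the last setting 3, while all 28 remained with at least 30 counts, where the cause was not tested. At an unadjusted p below 0.05 edgeR gave 602 and DESeq2 379. With the replicate block 45 circRNAs were called, 15 of them shared with the 28, and 26 loci. It left 0 miRNA sets passing. Since no sign was seen that the numbers pair the rats, neither result is read as stronger or weaker. Leaving out 1 library each gave 15 calls (without saline replicate 1) to 40 (without CFA replicate 3), of which 6 and 20 were among the 28; for the other libraries 13 to 17 were. The cause of these shifts was not tested.

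The 1 locus was also the 1 call with RLE, total counts and DESeq2, and 1 locus was called when circRNAs were joined by shared junction ends, where its identity was not compared. There were 4 loci without a filter and 0 with filterByExpr, at least 30 counts, a fit that is not robust or reads in all 6 libraries (78, 104, 136 and 98 at an unadjusted p below 0.05 in edgeR). Leaving out 1 library each gave 0 to 3 loci. At an unadjusted p below 0.05 edgeR gave 125 loci and DESeq2 134. The 9 other ways of splitting the 6 libraries gave 160 to 512 loci in edgeR at this threshold. The cause was not tested.

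For circRNAs seen at equal depth, the difference (CFA minus saline) was -1130, with -636 at 2 or more reads and -1319 without thinning; without 1 library it ran from -2995 to 198, the latter without saline replicate 2, the cause not tested. Long circRNAs kept their lower share in CFA in 8 of 8 settings, and so did unspliced ones. No miRNA set passed in any setting of camera, where 0 or 1 set had an unadjusted p below 0.05. The medians of the miR-146 and miR-21 sets turned to -0.12 and -0.11 with 1 or more matches, which makes the sets far wider. Leaving out 1 library each, they ran from 0.11 (without CFA replicate 3) to 0.51 and from 0.24 (without CFA replicate 1) to 0.84. Of the 4 named identifiers, novel_circ_0006907 lost its call in 2 of 15 settings and novel_circ_0028195 in 2 of 14, both with filterByExpr and at least 30 counts; novel_circ_0011300 lost it in 5 of 15 and novel_circ_0005029 in 10 of 15. The 354 nt and 385 nt circles of chromosome 3 lost it in 9 and 7 of 16, and the 678 nt circle, not among the 28, passed in 3 of 16. None of these changed direction. Tests on host genes and host gene lists, and their alternatives, were not run, because identifiers are not paired with names. At this depth and spread the simulated recovery of 4-fold changes was 19.4% for well-read circRNAs, so smaller changes can be missed.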

Other observations

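Except for the search for near-identical junctions, for shared sequence and for 1 dominant locus in the miR-146 set, the tests in this part were chosen after the results were seen. On biology outside the comparison, circRNAs of the Y chromosome were read in all 6 libraries, 29 circRNAs in all. Of circRNAs with reads in all 6 libraries, 94.0% had a log2 fold change within 1 of 0. Of the circRNAs with at least 10 reads in 3 libraries and none in the other 3, 8 were read in saline rats alone and 1 in CFA rats alone, while the 18 other triplets of libraries had 1 to 19. Circles of the same locus were weakly correlated in their changes. Over 1545 loci with at least 2 well-read circles, Pearson's r between the log2 fold changes of siblings was 0.0839 for CFA against saline, and 0.0806 to 0.281 for the 9 other ways of splitting the 6 libraries, 8 of which were higher. If most host loci responded to CFA as a whole, the real split was to stand above the others, and it did not. A response of some loci need not raise r over 1545 loci. With only 10 splits this ranking does not decide the question.

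The 28 circRNA calls were weighed as a first pattern, since 21 of them are all-or-none. Near-identical junctions that take each other's reads are argued against, since 1 of the 28 has such a neighbour. Zeros that strike single libraries regardless of group stay open and may account for as many calls: after each circRNA's values were shuffled over the libraries, 15 of 20 shuffles gave 28 or more calls, with a range of 18 to 53. The 10 splits of 6 libraries are too few for a share below 0.05; 7 of them gave as many calls, the real one gave 28 and the highest other 86, a split of CFA replicates 1 and 2 with saline replicate 3, which may point to a structure of the samples, although what sets this split apart was not tested. An effect of CFA on single circRNAs also stays open, as a hypothesis. The 3 calls that held whichever library was left out had at least 20 reads in each saline library and none in CFA libraries. Other triplets of libraries had 0 to 6 circRNAs of this all-or-none kind, so holding without any 1 library does not point to CFA.

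As a second pattern, unspliced segments made up 7 of 14 lower and 0 of 14 higher calls. Deeper saline libraries stay open: after thinning the share of unspliced circRNAs among those seen differed by -0.219 percentage points (CFA minus saline). At the 1 read used here, thinning removed only 2.43% of the circRNAs of the deepest library, so it does not test depth. At 2 reads or more the deepest library fell from 21677 to 19460 circRNAs, but the unspliced share was not computed there. The unthinned share did not follow depth: it was highest in saline replicate 1, the smallest library (573696 reads), at 2.46%. It was lowest in CFA replicate 3 (903443 reads), at 2.11%. The share of reads in unspliced circRNAs, in contrast, was highest in the deepest library, saline replicate 2, at 7.46%. In saline replicate 1, less deep than every CFA library, the 7 lower segments had 32, 33, 0, 30, 0, 0 and 30 reads. All 7 were at 0 in the CFA libraries. They were called for this difference, so no verdict on the set is drawn from these values. Segments that come and go in any library, by whatever route, are consistent with the other splits, where a median of 16.3% and up to 28% of the calls were unspliced, against 25% in the real split and 2.50% of the circRNAs tested. Of the 46 circRNAs with at least 30 reads in 1 library and none elsewhere, 14 were unspliced (30.4%). An effect of CFA on such segments stays open and was not tested beyond this.

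The locus on chromosome 3 was weighed as the last pattern, because 3 of its circles with a shared end had larger values in CFA. CFA replicate 1 as the whole cause stays open: without it each of the 3 log2 fold changes was above 0, the least at 2.13 times its SE, but the 3 were chosen for their higher values, and the 678 nt circle of CFA replicate 3, at 77.5 RPM, lay below saline replicates 1 and 2, at 145 and 96.9 RPM. For a change of the whole locus by the same amount, the 11 other tested circles had a median log2 fold change of 0.40 (95% bootstrap interval -0.06 to 0.79). The 3 set aside have the largest values of the 14, so the others are lower by construction, and the interval resamples circles, not rats. This median therefore decides nothing. The most-read of the 11, a 386 nt circle, was at -0.35 ± 0.31 (SE), so a rise was not seen in every circle. Shared sequence is argued against, with 0 circRNAs of other loci that hold a 25-mer of the 3. A choice of certain circles of this locus in CFA rats remains a hypothesis, since it rests on 3 rats per group. Leaving out any 1 library other than CFA replicate 1 gave log2 fold changes of at least 2.02 (354 nt) and 2.26 (385 nt). The call of the 354 nt circle was nonetheless lost without CFA replicate 2 or any 1 saline replicate. That of the 385 nt circle was lost without saline replicate 1 or 3.

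The miR-146 set was taken up after it was seen to be the 1 set of 15 with an unadjusted p below 0.05 in camera. A hypothesis that circRNAs with sites for miR-146, which restrains inflammatory signalling, are higher after CFA was thus raised by these values. The percentiles and splits given here re-use them without correction for the choice, so they are no independent test. The set's median log2 fold change of 0.48 lay at percentile 99.9 of random sets matched on length. Yet camera's adjusted p was 0.441 and the median was 0.11 without CFA replicate 3. A single locus with several members does not carry it: with each of the 16 loci counted once the median was 0.49, at percentile 99.2 of random sets of loci. The 10 splits are too few for a share below 0.05; 1 of them, the real one, gave a median this far from 0, and the highest other was 0.427. With 1 or more matches the median was -0.12, so the higher values are not shared by circRNAs with fewer sites. For the comparison of loci, 8 of 10 splits gave at least 1 call, the real one 1 and the highest other 19, and for the miRNA sets all 10 gave 0, the highest other 0; with 10 splits neither share can be under 0.05.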
